A study of Homo sapiens with 2 samples.

How the data were processed

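DNA methylation was measured with Methyl-MAPS in 2 established human breast cancer cell lines, MCF7 and T47D, with 1 library for each line. Both lines are luminal and express oestrogen receptor. Neither line was treated, per the labels' protocols. In Methyl-MAPS, genomic DNA is divided between a pair of digestions. McrBC cuts methylated DNA, so the long fragments that it leaves form the unmethylated compartment. The enzymes HpaII, HhaI, AciI, BstUI and HpyCH4IV cut at their sites only when these are unmethylated, so the long fragments that these 5 enzymes leave form the methylated compartment. Fragments longer than 800 bp were kept and both of their ends were sequenced as SOLiD mate pairs with at least 25 bp of genomic tag, per the labels' protocols. Because the fragments are long, 1 fragment reports on every assayed CpG between its ends, and neighbouring CpGs share fragments. Size selection and the need for an uncut fragment mean that a compartment holds only fragments in which no site was cut. Intermediate levels can therefore reflect mixtures of fragments, and short unmethylated stretches inside methylated DNA can be blurred.

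The deposited table of each library had no header and listed 1 CpG per line with its chromosome, its position, a methylation level as a fraction from 0 to 1, and the count of fragments covering it. Coordinates are on build hg18, per the submitters' processing notes. The aligner, the read filters, the rule that assigned fragments to CpGs, any balancing of the compartments and whether positions count from 0 or 1 are not given in the sources used here. Positions were taken as counting from 1. The product of the deposited fraction and the deposited fragment count was whole within 0.01 for 100% of the lines of both libraries. The methylated and unmethylated fragment counts were recovered from that product, and levels were then computed from these counts and expressed in percent.

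The deposited counts covered 8171301 CpGs in MCF7, with a median of 24 fragments per CpG and a range from 4 to 77 between the 5th and 95th percentiles. They covered 8098763 CpGs in T47D, with a median of 18 fragments and a range from 2 to 55. Together 8240958 CpGs were listed, and 8029106 were listed in both libraries. All comparisons used the 7008422 CpGs with at least 5 fragments in both libraries, 85.0% of those listed. A CpG at that minimum has a level known only in steps of 20 percentage points, so single CpGs were described as distributions and regions were used for tests.

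Levels were summarised over all CpGs used, by the number of listed CpGs within 500 bp on each side (the CpG itself included), by chromosome, in fixed windows of 1 kb with at least 3 CpGs, in CpG clusters and in fixed blocks of 100 kb with at least 50 CpGs. CpG clusters stood in for CpG islands. They were runs of listed CpGs with gaps of at most 50 bp, a length of at least 200 bp and at least 15 listed CpGs, of which at least 5 were used. The tables list only part of the genome's CpGs, so these clusters differ from annotated islands. The level of a region was the mean over its CpGs. The number of fragments of a region was the median coverage of its CpGs and not the sum, because a fragment covers several CpGs.

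Windows and clusters were compared by two-sided Fisher's exact tests on methylated and unmethylated fragments, with Benjamini-Hochberg adjustment over all regions of the same kind. The methylated number of a region was its mean level times its fragment number, rounded to a whole number. Tests and intervals thus rest on these derived numbers and not on fragments counted over the region. A region was called different when its adjusted p was under 0.05 and its levels lay at least 50 percentage points apart. These tests compare 2 libraries and not the cell lines as populations, since neither line was sampled again. Library amplification was not controlled by molecular identifiers, so p-values and intervals cover counting error only. Blocks, density classes and chromosomes had no test. A block was counted as different at 25 percentage points or more. Intervals of single regions are 95% Wilson intervals. The standard errors of genome means are jackknife errors over chromosomes, which describe variation along the genome. Regions named in the text were the 10 with the largest difference in each direction among those called, with ties broken by the fragment number of the shallower library and then by the number of CpGs. This rule, the minimums and the thresholds were set before the data were examined.

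The calling procedure was tested on simulated data drawn at the real depths. Of 100 simulated 1 kb windows changed by 60 percentage points it recovered 41%, and of 100 changed by 90 points it recovered 80%. For CpG clusters the shares were 56% and 90%. No unchanged window or cluster was called in these simulations, which drew counting error only. Few regions were changed in the simulations, so the adjustment was stricter there than in the data, where 126028 windows passed it. The recovered shares therefore do not measure how complete the calls in the data are. Calls can still miss differences, more so for smaller differences and lower depths.

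The alternatives were coverage minimums of 3 and 10, an upper limit on coverage at percentile 99.9, thinning of MCF7 to the depth of T47D, the deposited fraction in place of the count ratio, scaling of both compartments to equal totals in each library, other thresholds of difference, other region sizes, the smallest coverage as the fragment number, no test, autosomes alone and subtraction of the median difference. Quantile matching of both libraries was added after the data had been seen, as was equal-total scaling for blocks, density classes and chromosomes. The thinning drew fragments separately at each CpG and so did not keep the sharing of fragments between neighbours.

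Gene promoters and gene lists had been planned but were not analysed here, because the gene annotation at hand belonged to GRCh38.p14 and coordinates were not converted between builds. Regions are therefore given by position, without gene names. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0, and figures used matplotlib 3.10.9.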

Results

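The data collected were genome-wide DNA methylation levels of MCF7 and T47D cells, compared to describe how the methylation landscapes of a pair of oestrogen receptor positive breast cancer lines differ. There was 1 library per line, so no value below has a replicate error, and a difference between the libraries cannot be set against the spread within a line. MCF7 was covered more deeply, with a mean of 31.3 fragments per listed CpG against 21.8 in T47D. The excess lay in the methylated compartment. MCF7 had a mean of 17.3 methylated and 14.0 unmethylated fragments per CpG, and T47D had 8.34 and 13.5. Summed over CpGs, methylated fragments made up 55.3% of the MCF7 coverage and 38.2% of the T47D coverage. The level of a CpG depends on the ratio of the compartments, and their balance before sequencing is not given in the sources used here. Absolute levels and the overall offset between the lines therefore carry an uncertainty that the counts do not show.

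With levels as deposited, T47D was less methylated than MCF7 over most of the genome. The mean level of the 7008422 CpGs was 54.3% in MCF7 (jackknife SE over chromosomes 0.552) and 40.1% in T47D (0.266), a difference of 14.1 percentage points (0.430). With both compartments scaled to equal totals in each library the means were 51.2% and 47.6%, and the difference fell to 3.67 points. The median CpG was at 61.1% in MCF7 and 38.5% in T47D. CpGs above 80% made up 29.0% of the total in MCF7 and 10.8% in T47D, while CpGs below 20% made up 22.4% and 32.2%. MCF7 was the higher line at 68.3% of CpGs and T47D at 27.0%. A difference of more than 50 points was found at 667267 CpGs (9.52%) in the direction of MCF7 and at 76571 (1.09%) in the direction of T47D. Scaling to equal totals changed these shares to 5.63% and 2.43%. Levels of the lines were correlated across CpGs (Pearson r = 0.636), although CpGs are not independent replicates.

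**Figure D1:**
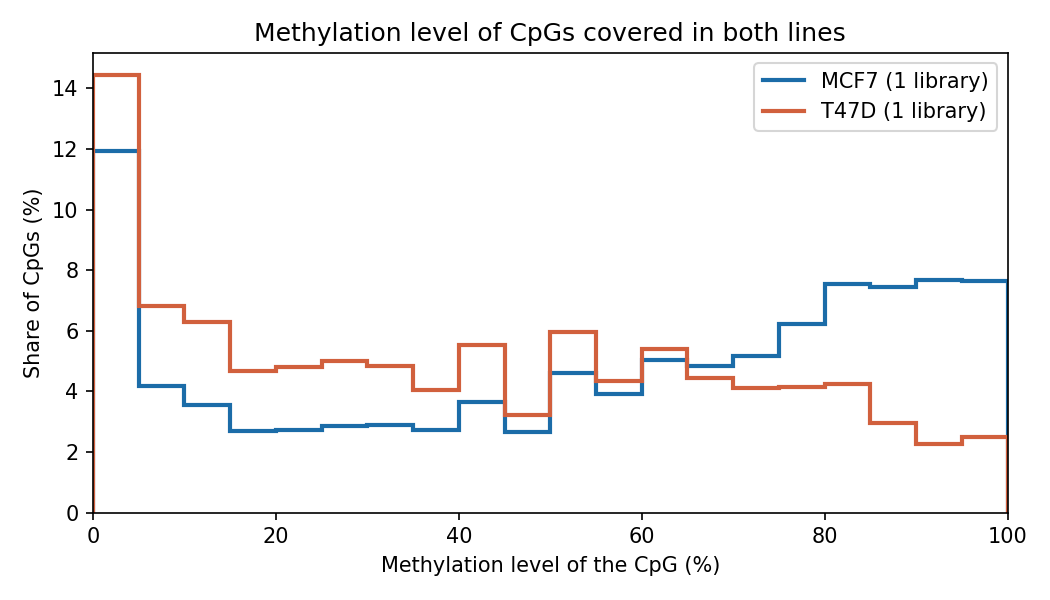
Distribution of methylation levels over the CpGs with at least 5 fragments in both lines. The horizontal axis is the level in percent in steps of 5 and the vertical axis the share of CpGs in percent, with 1 line per library. In MCF7 the share above 80% is 29.0% and in T47D 10.8%, while CpGs below 20% make up 22.4% and 32.2%.

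The dependence of methylation on CpG density had the same shape in both lines, low in the CpG-dense sequence and highest at intermediate density. CpGs with more than 40 listed CpGs within 500 bp had mean levels of 20.1% in MCF7 and 15.7% in T47D. CpGs with 6 to 10 neighbours counted this way had 70.5% and 51.2%, and those with 11 to 20 had 69.5% and 50.2%. In the sparsest class, with 1 to 5, the means were 51.2% and 38.4%. The difference between the lines was 19.3 points at 6 to 10 CpGs, 12.8 points at 1 to 5 and 4.36 points above 40. Under equal totals the sparsest class differed by 1.41 points, and in the densest class the direction turned, with a difference of -1.02 points (MCF7 minus T47D). At intermediate density, 46.1% of CpGs with 6 to 10 neighbours exceeded 80% in MCF7 and 16.6% did so in T47D. In the densest class 73.8% of MCF7 CpGs and 77.5% of T47D CpGs were below 20%.

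**Figure D2:**
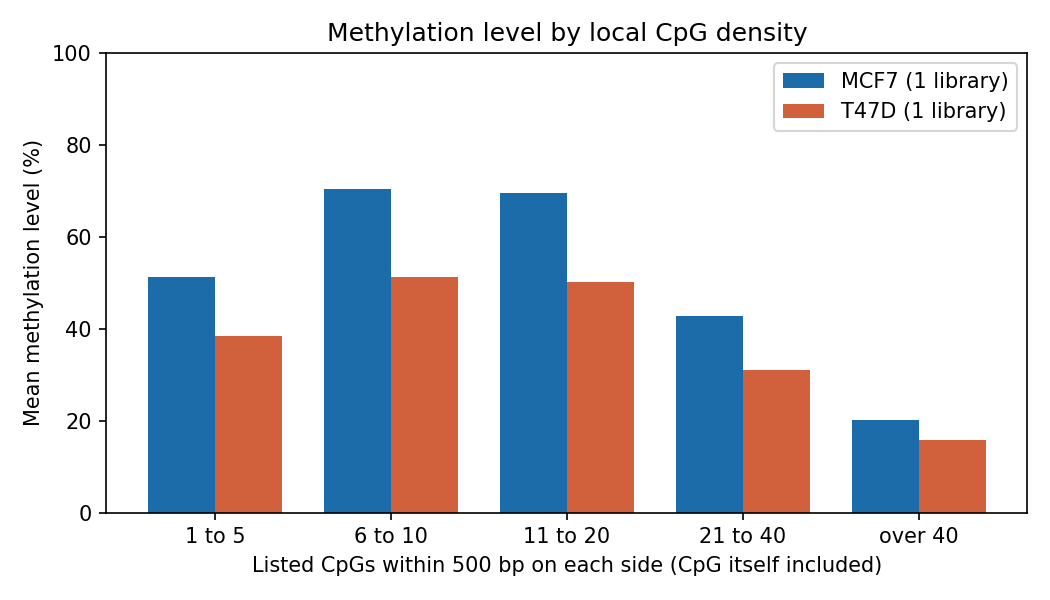
Mean methylation level in percent (vertical axis, bars from 0) by the number of listed CpGs within 500 bp on each side (horizontal axis), with 1 bar per library and class. MCF7 is higher in each class with levels as deposited, by 4.36 points in the densest class, where the direction turns under equal totals.

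Among CpG-dense clusters, most were at low levels in both lines, and the called differences were mostly in the direction of MCF7. Of 19981 CpG clusters, with a median length of 342 bp and a median of 27 listed CpGs, 16782 could be tested. Both lines were below 20% in 9592 of them (57.2%), and both were above 80% in 826 (4.92%). Levels lay within 10 points of each other in 57.3% of clusters. MCF7 was above 80% in 2863 clusters (17.1%) and T47D in 1058 (6.30%). A difference was called in 824 clusters with MCF7 higher and in 93 with T47D higher, by Fisher's exact test with Benjamini-Hochberg adjustment and a difference of at least 50 points. MCF7 was thus the higher line in 89.9% of calls, against 80.3% under equal totals (571 and 140 clusters) and 77.3% after quantile matching (495 and 145). The share also depended on the assumed balance beyond these scalings, and multiplying the T47D odds of methylation by 4 lowered it to 45.0% (485 and 593). The clusters called higher in MCF7 had a mean of 84.4% ± 11.6 (SD over 824 clusters) in MCF7 and 10.8% ± 11.9 in T47D. Those called higher in T47D had 6.52% ± 9.98 (SD over 93 clusters) in MCF7 and 81.8% ± 14.0 in T47D. Levels above 80% in MCF7 and below 20% in T47D occurred in 439 clusters, and the opposite in 53.

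The largest cluster differences were complete switches between full methylation and none. The deepest of those named in the direction of MCF7 lay at chromosome 10, positions 124900529 to 124900779. Its level was 99.85% of 43 fragments in MCF7 (95% interval 91.8 to 100) and 0% of 20 fragments in T47D (0 to 16.1), with an adjusted p of 3.89e-14 by Fisher's exact test. A cluster at chromosome 17, 76987939 to 76988254, with 44 CpGs, was at 99.85% of 14 fragments in MCF7 and 0% of 26 in T47D (upper bound 12.9). A cluster at chromosome X, 24933436 to 24933817, was at 99.84% of 21 fragments and 0% of 17 (upper bound 18.4). On chromosome 3, 129690944 to 129691188 was at 100% of 20 fragments in MCF7 and 0% of 8 in T47D, where the upper bound was 32.4. At chromosome 8, 143530343 to 143530746, the levels were 100% of 9 fragments and 0% of 10. In the direction of T47D, the deepest was at chromosome 19, 45812062 to 45812341, with 0% of 36 fragments in MCF7 (upper bound 9.64) and 100% of 20 in T47D (lower bound 83.9), at an adjusted p of 5.62e-13 by Fisher's exact test. At chromosome 7, 115637989 to 115638263, MCF7 had 0% of 12 fragments and T47D 99.3% of 16. At chromosome 13, 40930312 to 40930675, MCF7 had 0% of 18 fragments and T47D 94.3% of 17 (lower bound 73.0). Most of the others among the 20 named clusters rested on 5 to 8 fragments in at least 1 line. At chromosome 16, 62935307 to 62935681, MCF7 had 100% of 27 fragments and T47D 0% of 5 (upper bound 43.4).

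Called clusters were spread over the chromosomes. Called as higher in MCF7 were 7.16% of the clusters on chromosome 14, 6.99% on chromosome 10 and 6.97% on chromosome 3, compared with 2.34% on chromosome 22 and 2.59% on X. Some megabases held several called clusters, and those given here were chosen after their values were seen. Of these, 7 of the 60 tested clusters from 144000001 to 145000000 on chromosome 8 were called higher in MCF7, as were 6 of 24 from 50000001 to 51000000 on chromosome 12 and 5 of 11 from 199000001 to 200000000 on chromosome 3. In the direction of T47D no megabase held more than 2 called clusters. Both tested clusters were called higher in T47D in the megabases starting at 27000001 on chromosome 21, 182000001 on chromosome 3 and 87000001 on chromosome 5.

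Over the 1 kb windows, which cover mainly sequence outside the clusters, the mean difference was wider in percentage points, at higher levels in both lines. The clusters averaged 28.3% in MCF7 and 21.1% in T47D. The 860762 windows averaged 62.0% in MCF7 and 45.6% in T47D, at a median of 26 and 19 fragments. MCF7 exceeded 80% in 26.2% of windows and T47D in 7.11%. Fisher's exact test with Benjamini-Hochberg adjustment and the 50-point minimum called 53025 windows higher in MCF7 (6.16%) and 1687 higher in T47D (0.196%), so that MCF7 was higher in 96.9% of calls. Under equal totals 24666 and 3576 windows were called, 87.3% of them higher in MCF7. After quantile matching the numbers were 17454 and 4007, and the share was 81.3%. Of the 3576 windows higher in T47D under equal totals, 1588 were also called with levels as deposited. Chromosome 20 had the greatest share of windows called higher in MCF7, at 10.1%, followed by chromosome 22 at 8.47% and chromosome 8 at 7.31%. Chromosome X had 3.52%.

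All 10 windows named in the direction of MCF7 were at 100% in MCF7 and 0% in T47D. The deepest was at chromosome 14, 47213001 to 47214000, with 31 fragments in MCF7 (lower bound 89.0) and 15 in T47D (upper bound 20.4). Another pair lay on chromosome 1 at 2982001 to 2983000 (20 and 10 fragments) and at 3230001 to 3231000 (11 and 17). In the direction of T47D, the window at chromosome 1, 34883001 to 34884000, had 0% of 11 fragments in MCF7 and 100% of 15 in T47D, and a neighbour at 34906001 to 34907000 had 0% of 10 and 100% of 5. The window at chromosome 13, 99435001 to 99436000, with 56 CpGs, had 1.48% of 7 fragments in MCF7 and 99.6% of 10 in T47D. It overlaps the named cluster at 99435670 to 99435993, where the levels were 2.13% of 7 and 100% of 10.

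At the scale of 100 kb, with levels as deposited, more blocks averaged below 50% in T47D than in MCF7, and quantile matching turned this direction. Of 27948 blocks, 46.2% averaged below 50% in MCF7 and 86.9% in T47D. The median block was at 51.5% in MCF7 and 38.3% in T47D, and 10% of blocks lay below 25.5% and 20.7%. MCF7 was higher by at least 25 points in 3296 blocks and T47D in 66. This asymmetry depended on the scaling of the libraries. Both scalings reduce a genome-wide difference whether it is technical or real, so they cannot tell its source. Equal totals gave 55.3% and 63.4% of blocks below 50%, with 1144 blocks higher in MCF7 and 664 in T47D, and quantile matching gave 68.4% and 64.6% of blocks below 50%, with 714 blocks higher in MCF7 and 954 in T47D. Both comparisons turned direction under quantile matching. Block means were correlated between the lines (Pearson r = 0.602 across blocks, which are not replicates).

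The greatest block differences were near the start of chromosome 1, where T47D was almost unmethylated. From 3000001 to 3100000 the mean over 691 CpGs was 87.2% in MCF7 and 2.42% in T47D, at median depths of 20 and 11 fragments. From 2800001 to 2900000 the means were 82.2% and 1.77%, from 3100001 to 3200000 they were 87.1% and 6.62%, and from 3200001 to 3300000 they were 88.0% and 7.45%. In the adjacent blocks, which were chosen after their values were seen, T47D was at 17.4% from 2600001 to 2700000 (51 CpGs) and 41.6% from 3300001 to 3400000. Low T47D levels were also found further along, as from 4500001 to 4600000, where 129 CpGs averaged 63.3% in MCF7 and 0.877% in T47D. The median depths there were 29 and 6 fragments. Other blocks of this kind were chromosome 8, 143200001 to 143300000 (82.5% and 4.53%), chromosome 7, 157000001 to 157100000 (82.0% and 6.81%), chromosome 22, 47300001 to 47400000 (78.6% and 6.68%) and chromosome 10, 131500001 to 131600000 (80.2% and 8.31%). In the opposite direction the named differences were smaller. The largest outside chromosome Y was at chromosome 1, 143300001 to 143400000, with 35.9% in MCF7 and 73.4% in T47D. Its median depths were only 7 and 5 fragments. Chromosome 8, 5400001 to 5500000, had 13.9% in MCF7 and 48.6% in T47D. Chromosome 7, 115000001 to 115100000, had 17.0% and 51.7%, and chromosome 4, 114900001 to 115000000, had 23.4% and 57.2%. Of the 10 blocks named in that direction, 6 lay on chromosome Y, where few CpGs were covered. They included the largest, at 28.9% in MCF7 and 91.7% in T47D over 76 CpGs, with median depths of 6 and 5 fragments. Whether fragments placed on chromosome Y came from it was not tested.

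**Figure D3:**
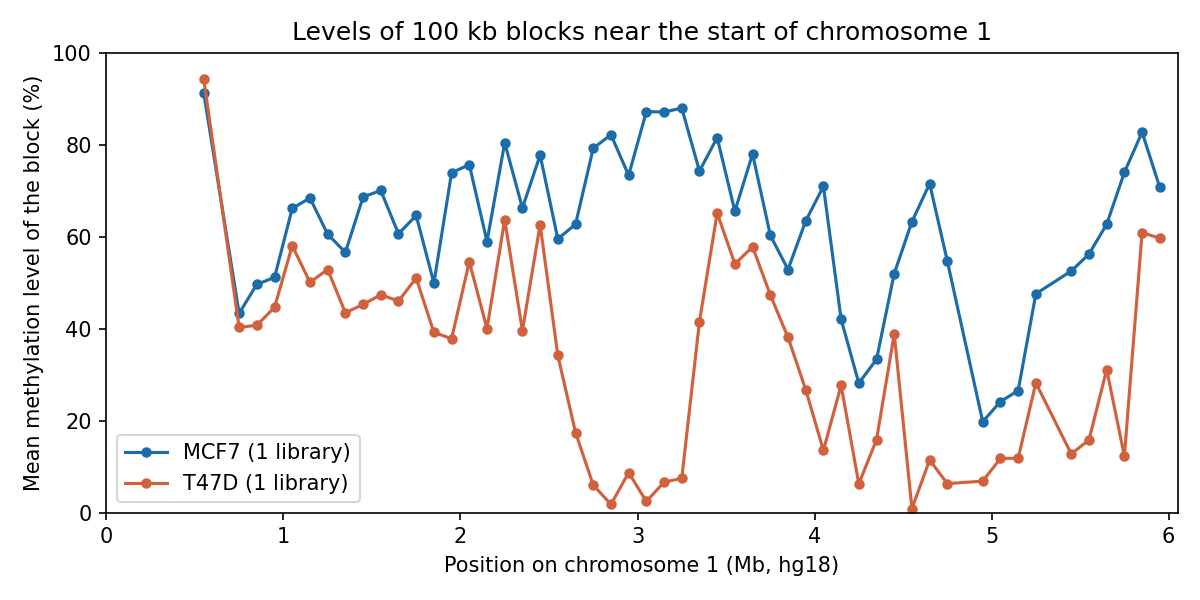
Mean methylation level in percent (vertical axis) of 100 kb blocks with at least 50 CpGs along the start of chromosome 1 (horizontal axis, Mb, hg18), with 1 point per block and library. From 2700001 to 3300000 T47D stays below 10% while MCF7 stays above 70%.

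With levels as deposited, the mean level was higher in MCF7 on 23 of 24 chromosomes. Under equal totals it was higher on 22, since chromosome 4 turned direction at 47.1% in MCF7 and 47.9% in T47D. Over the 23 chromosomes without Y, the mean difference was 14.3 points ± 2.37 (SD over chromosomes), and the SD of the chromosome means was 3.15 points in MCF7 and 1.51 points in T47D. The difference was greatest on chromosome 20, with 58.2% in MCF7 and 38.5% in T47D, and on chromosome 22, with 60.1% and 42.4%. It was smallest on chromosome 4 (50.1% and 40.7%) and on X (47.03% and 36.53%). The 10985 used CpGs listed on chromosome Y were the exception at 39.9% and 50.4%, and whether their fragments came from Y was not tested. Chromosome 20 was also the chromosome with the most uneven depth, with 80.9 fragments per CpG in MCF7 and 32.9 in T47D.

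**Figure D4:**
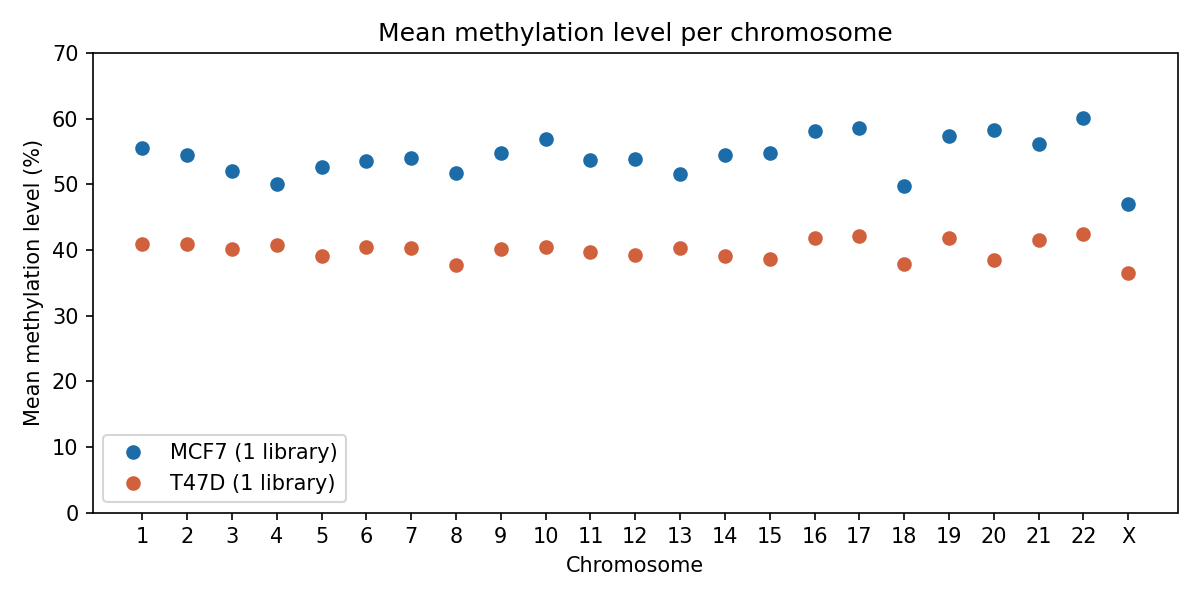
Mean methylation level in percent (vertical axis) of each chromosome other than Y (horizontal axis), with 1 point per library. MCF7 lies above T47D on each, with the widest gap on chromosome 20 at 19.7 points and the narrowest on chromosome 4 at 9.42 points, for levels as deposited; under equal totals chromosome 4 turns direction.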

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

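The uses of coverage and the tests of explanations in this part were chosen after the results had been seen, except the test of DNA left uncut by McrBC, whose prediction was set before its value was computed.

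Fragment counts, which the comparisons of methylation use for levels, tests and minimums but not as a measure of their own, differed strongly between the lines in some segments. In 167 blocks of 100 kb, MCF7 had at least 4 times the coverage of T47D in both compartments, each relative to its own median. The runs with the most such blocks were chromosome 3, 61600001 to 65000000, with a relative coverage 12.05 times that of T47D, chromosome 17, 55200001 to 57400000, with 10.4 times, and chromosome 20, 51600001 to 53000000, with 10.6 times. In 33 blocks T47D had at least 4 times the coverage, and runs of 6 such blocks lay at chromosome 11, 119800001 to 120800000, and chromosome 4, 182000001 to 182600000. Chromosome Y was left out of these counts. Methylation in the MCF7 blocks differed by 15.9 points on average (45.6% in MCF7 and 29.7% in T47D over 156 blocks with a level).

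A few segments had almost no fragments in only 1 line. At chromosome 4, 182200001 to 182500000, fragments summed over 626 listed CpGs numbered 390 in MCF7 and 11636 in T47D. At chromosome 18, 2900001 to 3000000, T47D had 60 and MCF7 8436. At chromosome X, 96200001 to 96300000, the sums were 134 in T47D and 4349 in MCF7, and at chromosome 19, 20400001 to 20500000, they were 161 and 4299. Such sums count a fragment once for each CpG it covers.

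The first pattern weighed was the lower level of T47D across the genome. After the single factor of 2.21 between the compartments that set the median window difference to 0, 26904 windows still differed (21380 higher in MCF7, 5524 in T47D). One factor with counting error alone thus left differing windows in both directions. Noise between libraries of one line was not measured, so a factor together with such noise stayed open. The mean offset itself stayed open, because equal totals reduced it to 3.67 points and the true balance is not known. Methylated DNA left uncut by McrBC at one rate in T47D also stayed open: of the windows above 80% in MCF7 with at least 20 T47D fragments, 5.01% (95% Wilson interval 4.88 to 5.14) lay above the ceiling of 73.9% that it allows by more than counting error, against a line of 5% set beforehand and at most 2.5% by chance, and a difference between the cell lines themselves was not tested for want of replicates.

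The second pattern was long stretches near 0 in T47D that were methylated in MCF7. Outside chromosome Y, in 108 blocks of 100 kb MCF7 exceeded 60% and T47D was below 15%, and 0 blocks showed the opposite (38 and 0 under equal totals, 32 and 0 after quantile matching), while on Y 1 of 55 blocks showed the opposite with levels as deposited. The longest runs were chromosome 8, 142600001 to 143300000 (73.6% and 7.82%), and chromosome 1, 2700001 to 3300000 (82.9% and 5.50%). Among all 7083 blocks above 60% in MCF7, the single balance factor of 2.17 that fits their median predicted at least 40.9% in T47D. With the counting error of the median coverage, it gave 33.2 blocks below 15% in T47D (upper counting limit 45) against the 108 seen. That error overstates the counting error of a whole block. One factor with counting error alone thus fell short of these stretches. A factor together with noise between libraries of one line stayed open, because that noise was not measured. Loss of methylated copies from T47D cannot be told apart from loss of methylation, because the fragments carry no allele information here: unmethylated T47D coverage was 0.943 times its autosomal median, with 14 blocks below 0.5 times, and coverage of both compartments together was 0.659 times.

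The third pattern was the excess of CpG clusters higher in MCF7 among those that differed. The balance of the compartments stayed open: 80.3% (95% Wilson interval 77.2 to 83.1) were higher in MCF7 after scaling to equal totals, but a factor of 3 on the T47D odds gave 59.2% and a factor of 4 gave 45.0%, with mean CpG differences of -2.57 and -6.63 points, and the true balance is not known. After thinning, 90.4% were higher in MCF7. Thinning drew both compartments at the same rate and so kept their ratio and the direction of the differences. It therefore cannot decide whether the greater depth of MCF7, which lay in the methylated compartment, caused the excess. A difference in methylation between the cell lines stays open as a hypothesis, found and tested on the same 2 libraries.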

How the results depend on the processing

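The alternatives were planned, except quantile matching and the equal-total scaling of blocks, density classes and chromosomes, which were chosen after seeing the data. Of the summary values under their alternatives, 63 stayed within their counting interval or within 1.5 times the main count, 69 moved and 1 changed sign. Taken as pairs of values for MCF7 and T47D, the share of blocks under 50% and the numbers of differing blocks also turned direction under quantile matching. The number of chromosomes with a higher MCF7 mean fell from 23 to 22 under equal totals, since chromosome 4 turned direction (-0.832 points). The cause of each move was not tested unless the alternative's construction gives it. The upper limit on coverage and the deposited fraction moved no summary value by that measure. For the 40 named windows and clusters, 405 alternatives gave the same call and 2 lost it. Both losses were at a coverage minimum of 3 (differences of 99.2 and -90.0 points at clusters on chromosomes 11 and 9). The named regions were chosen for the largest differences. Other thresholds of difference, leaving out the test and the deposited fraction could therefore hardly change their calls. Equal totals and quantile matching also barely move levels at the ends of the scale. The 405 same calls thus cannot measure how stable these regions are. At a minimum of 10, the 14 regions with a value kept their call. No value was available for 26 named regions at a minimum of 10, or for 7 after thinning, because too few CpGs were left. No paired analysis was possible because each line had 1 library, and no library could be left out. Promoters and gene lists were not run for want of an annotation of the build.

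Equal totals changed the mean levels to 51.2% in MCF7 and 47.6% in T47D (difference 3.67 points), the shares of CpGs over 50 points apart to 5.63% and 2.43%, the called windows to 24666 and 3576, and the called clusters higher in T47D to 140. The same scaling gave 55.3% and 63.4% of blocks under 50%, and 1144 and 664 blocks at least 25 points higher in MCF7 and T47D. By density it gave 1.41 points at 1 to 5 listed CpGs and -1.02 points above 40, where the direction turned. Quantile matching gave 4.37% and 2.79% of CpGs, 17454 and 4007 windows, 495 and 145 clusters, 68.4% and 64.6% of blocks under 50%, and 714 and 954 differing blocks. Subtracting the median difference gave 5.43% and 2.25% of CpGs.

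A coverage minimum of 3 gave means of 54.2% and 40.1%, 45.0% and 86.1% of blocks under 50%, and density differences of 12.5 points in the sparsest and 4.84 in the densest class. A minimum of 10 gave 54.1% in MCF7, a difference of 14.0 points, 1090 windows higher in T47D, 48.8% and 88.0% of blocks under 50%, and density differences of 13.1 and 3.55 points. Thinning gave 54.5% and 40.2% (14.4 points), and autosomes alone gave 54.5% and 40.2% (14.3 points). The shifts of the means are below 0.5 points and exceed only very narrow counting intervals, which treat CpGs as independent. Other shifts were larger. At a minimum of 10, windows higher in T47D fell from 1687 to 1090, and MCF7 blocks under 50% rose from 46.2% to 48.8%.

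Region definitions changed counts by construction. With a minimum difference of 25 points, 117377 and 3983 windows were called, and with 75 points 9553 and 272 windows and 387 and 49 clusters. Windows of 2 kb gave 30876 and 989 calls, at least 1 CpG gave 111862 and 15273, and at least 5 CpGs gave 31003 and 786. The smallest coverage as fragment number gave 1015 windows higher in T47D. Without a test, 3195 windows and 149 clusters were higher in T47D. A cluster gap of 100 bp gave 1641 and 153 clusters, and at least 30 listed CpGs gave 257 and 37. Blocks of 500 kb gave 41.7% and 94.7% under 50%, with 416 and 2 differing, and CpGs outside clusters gave 40.9% and 84.0%.

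Depth limited what could be said of single regions. Many named regions rest on 5 to 8 fragments in at least 1 line. Some do so in both, as the cluster at chromosome 11, 1368189 to 1368752, with 5 fragments in MCF7 and 6 in T47D. Simulated 1 kb windows changed by 60 points were recovered in 41% of cases, under an adjustment stricter than in the data.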

Other observations

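The test and the scalings in this part were chosen after the results they concern had been seen.

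The block difference depended on how many CpGs a block held. Blocks outside chromosome Y were divided into 5 groups of about equal number. In the group with the fewest used CpGs (50 to 115), MCF7 averaged 32.2% and T47D 26.5%, a difference of 5.66 points with an SD of 14.1 over 5593 blocks. In the group with the most (358 to 2030), the means were 59.7% and 42.5%, a difference of 17.2 points with an SD of 10.5 over 5560 blocks. Under equal totals the differences were -2.71 and 6.56 points, and after quantile matching they were -4.97 and 2.64 points. With levels as deposited MCF7 was thus the higher line in both groups, while under both scalings the difference was negative in the sparsest group. Both scalings lower the mean difference across the genome. The sign within a group therefore depends on the scaling and cannot tell which line is higher there. The difference was larger in the densest group in each case.

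CpG clusters called higher in MCF7 lay in sequence where MCF7 exceeded T47D by more than around other clusters. The hypothesis was that clusters differ where the sequence around them differs. Outside clusters, the surrounding 100 kb block differed by a median of 21.3 points for the 824 clusters called higher in MCF7, by 14.8 points for clusters not called and by 9.93 points for the 93 called higher in T47D. In 10000 random lists of 824 clusters, drawn singly from those not called higher in T47D, the median ranged from 14.1 to 16.2 points. Clusters in the same block share its value, so this range can be too narrow, and the lists were not matched on level. Of the clusters called higher in MCF7, 35.2% lay in blocks at least 25 points higher in MCF7, against 9.41% of those not called (12.7% and 1.99% under equal totals, 9.34% and 1.26% after quantile matching). For the same clusters, equal totals gave medians of 10.3, 3.84 and -1.21 points in that order, with random lists from 2.96 to 5.08. Quantile matching gave 5.93, -0.182 and -4.81 points, with random lists from -1.11 to 0.884. The order of the medians was thus the same with levels as deposited and under both scalings. The sign around clusters higher in T47D turned under both scalings, and that around clusters not called turned under quantile matching. This is a description of these 2 libraries, and it may include fragments that span a cluster and its flanks.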
